A study of Mus musculus with 4 samples.

How the data were processed

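H3K9me3, a histone mark of silenced chromatin, was profiled by native chromatin immunoprecipitation and sequencing in cultured mouse muscle stem cells. The cells carried loxP-flanked copies of Setdb1, an H3K9 methyltransferase gene, and a tamoxifen-inducible Cre recombinase under Pax7. Per the labels, 1 culture received ethanol (control) and 1 received 4-hydroxytamoxifen, which induces the deletion, and treatment lasted 72 h. Chromatin was cut with micrococcal nuclease and 8 µg was used per immunoprecipitation, per the labels' protocols. The 4 libraries were 1 H3K9me3 and 1 input library per condition. The input libraries were not analysed here.

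The deposited files were 2 lists of broad peaks. BWA 0.7.17-r1188, MACS2, ChIPseeker 1.30.3 and the genome build mm10 are named in the submitters' processing notes. The MACS2 version, its settings, the use of the input libraries and any pooling were not given in the sources used here. Each deposited peak carries the authors' fold enrichment, a linear ratio, and the authors' −log10 p-value and −log10 q-value. Fold and q were used to describe, rank or filter peaks within a list. Read depth is unknown, so a difference in depth between the libraries cannot be separated from a difference in the mark. The replicate number in the peak names differed from that in the sample labels, so the lists were assigned by condition.

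Peaks on chromosomes 1 to 19, X and Y were analysed. Peaks on unplaced scaffolds were set aside. Overlap was computed with bedtools 2.31.1 at a minimum of 1 bp, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Shares of peaks carry 95% Wilson intervals, which cover counting error only. Each overlap was set beside 100 random rotations of the other list within chromosomes. With 1 library per group there is no replicate check on any difference, and no p-value was computed.

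Gene positions came from a RefSeq table of assembly GRCm38.p6, whose chromosomes are those of mm10. The table gave no strand, exons or introns, so transcription start sites could not be placed. Windows of 3 kb on either side of both gene ends replaced the planned promoter windows, and a gene window was the gene plus 5 kb on both sides. Peaks were classed by midpoint as inside a protein-coding gene, inside another gene only, within 5 kb of a gene, or elsewhere. Repeat content was not analysed here, since no genome sequence was used.

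Before the data were examined, 17 gene lists and the rule for named genes were fixed. The rule took the 12 protein-coding genes with the highest sum of fold times overlapped bases at the gene ends in the control list and no deleted-list peak there. It took 8 by the same sum in the deleted list with no control peak there. It also took the members of each list with the largest fall and rise of window coverage over 10 percentage points, and always Setdb1, Pax7, Myod1 and Myog. Predicted genes were skipped in the first 2 parts. The regions named were the 5 peaks of highest fold present in 1 list alone, and the 5 bins of 100 kb with the largest loss and gain. Each list's mean change in covered percent was placed as a percentile among 10000 random gene lists of the same size, matched on control coverage and window length. These were drawn with replacement from the protein-coding genes and list members. The genes of the list itself were not left out, so the random lists are not independent of a large list. A list was said to lie outside the central 95% below 2.5 or above 97.5, and 0.85 of 17 lists of independent genes would do so by chance, which does not allow for clustered genes that share peaks. The percentile describes this pair of libraries.

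The list statistic was tested on simulated data, a copy of the control list of 105709 peaks. Peaks of the copy were dropped at random, and all peaks of the last autosome were removed. A planted loss of all peaks in the windows of 100 covered genes gave a percentile of 0, and an unplanted list gave 33.5. Smaller losses were not simulated, so differences of the sizes reported below were not tested in this way. Between the deposited control and deleted lists, 11 of 200 random lists of 50 genes (5.50%) lay outside the central 95%. Alternatives covered the peak threshold, peak joining, the overlap rule, list size, windows, bins and chromosomes. Those without chromosomes 6, 14, X and Y, at −log10 q of 2 or more, with 20000 peaks per list and with matching on gene density were chosen after seeing the data.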

Results

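H3K9me3 peaks were compared between cultured mouse muscle stem cells treated with ethanol (control) and cells treated with 4-hydroxytamoxifen to delete Setdb1, which encodes an H3K9 methyltransferase. The question was where the mark was found with and without the enzyme. There was 1 H3K9me3 library per condition, so no difference below has a replicate check. The control list held 105709 peaks on the main chromosomes and the deleted list 113503. The peaks covered 133 Mb (5.02%) and 134 Mb (5.03%) of the chromosomes. Median peak width was 904 bp in the control list and 854 bp in the deleted list. The median of the authors' fold enrichment was 2.57 and 2.59, each within its own list. Sequencing depth is unknown.

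Setdb1 itself lies on chromosome 3 from 95323525 to 95357202 (mm10). Peaks covered 0.888% of its window in the control list and 0% in the deleted list, which does not measure whether the gene was cut. Pax7, the gene that drives the Cre, and Myod1 and Myog, which encode muscle transcription factors, had no peak in their windows in either list. The deleted list had 7794 more peaks than the control list, and this direction depended on the threshold. At the authors' −log10 q of 2 or more, 19912 control peaks and 13039 deleted-list peaks remained, and at 3 or more, 1937 and 1120.

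Chromosome 6 and chromosome X differed most between the lists. Peaks covered 10.5% of chromosome 6 in the control list and 5.28% in the deleted list, a deleted-to-control ratio of 0.504. Chromosome X was covered at 1.15% in the control list and 2.61% in the deleted list, a ratio of 2.26. The sex and chromosome number of the cultures, on which both ratios could depend, were not given in the sources used here. Chromosome 14 was sparsely covered in both lists, at 0.390% and 0.330%, with 654 and 568 peaks. Chromosome Y held 14 and 16 peaks. The other 17 autosomes had ratios from 0.922 on chromosome 3 to 1.23 on chromosome 7, and 12 of them were covered more in the deleted list.

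**Figure D1:**
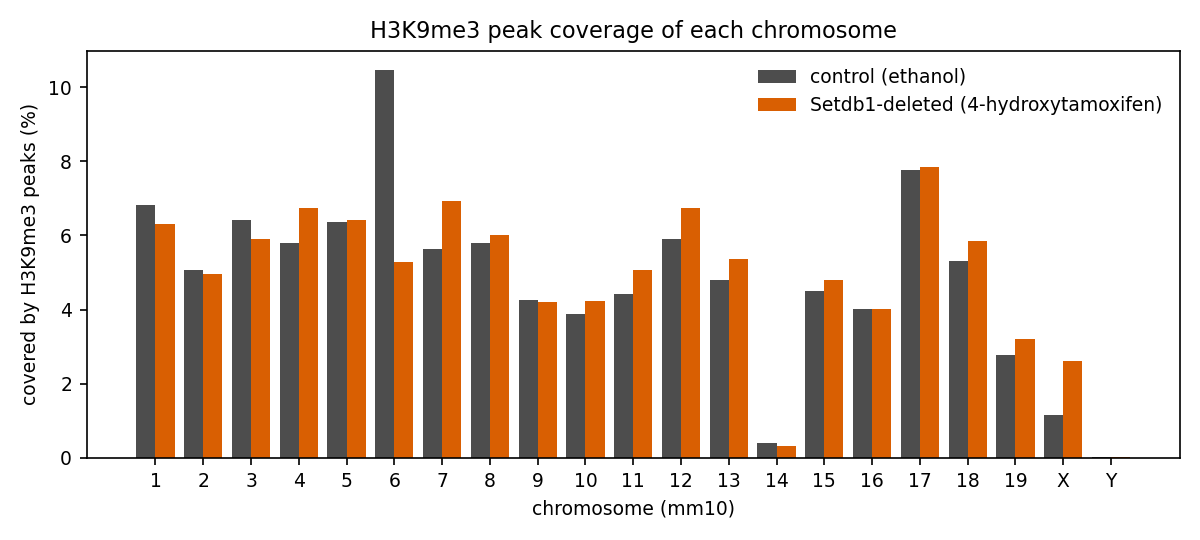
Percent of each mm10 chromosome (x axis) covered by H3K9me3 peaks (y axis) in the control list (grey bars) and the deleted list (orange bars), with 1 library per group and no error bars. Chromosome 6 stood at 10.5% and 5.28%, X at 1.15% and 2.61%, and chromosome 14 under 1% in both lists.

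The differences ran along the whole of chromosomes 6 and X. All 14 full segments of 10 Mb on chromosome 6 had ratios between 0.397 and 0.627. All 17 segments of X had ratios between 1.80 and 2.78. Among 211 segments of the other 17 autosomes, 90% of ratios lay between 0.855 and 1.55. Covered length over those autosomes was 116 Mb in the control list and 121 Mb in the deleted list, a ratio of 1.05. Without X and Y the total covered length was slightly lower in the deleted list, with a log2 deleted-to-control ratio of -0.0225.

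**Figure D2:**
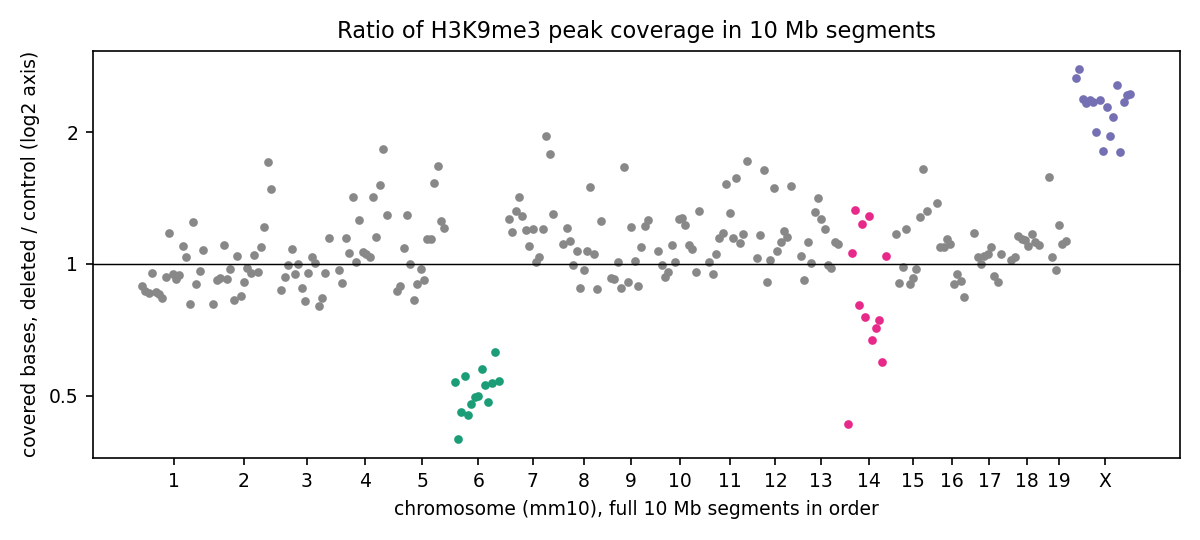
Ratio of bases covered by H3K9me3 peaks, deleted over control (y axis, log2 scale), in full 10 Mb segments in order along chromosomes 1 to 19 and X (x axis); each point is 1 segment, with chromosome 6 in green, 14 in pink, X in violet and the rest in grey. The 14 points of chromosome 6 lie between 0.397 and 0.627 and the 17 of X between 1.80 and 2.78.

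Of the control peaks, 49679 (47.0%, Wilson interval 46.7 to 47.3%) had no overlapping peak in the deleted list. Of the deleted-list peaks, 56630 (49.9%, 49.6 to 50.2%) had no control peak. Random rotations left 88.8% and 89.5% without a partner on average. The lists shared 49.8 Mb, which was 22.9% of the bases in either list, against 2.96% after rotation. Sharing was greater among peaks of higher confidence. From the lowest to the highest class of −log10 q, the shared percent went from 38.2% to 91.8% in the control list and from 36.3% to 89.2% in the deleted list. Unshared peaks were narrower, with a median width of 658 bp against 1202 bp for shared peaks in the control list and 640 bp against 1139 bp in the deleted list. Under a rule of 1 bp a wider peak meets a peak of the other list more easily. How much of the difference in width comes from that rule was not tested. The share without a partner depended strongly on the rule. It was 15.5% and 17.9% when a peak within 5 kb counted, and 87.1% and 77.9% when both lists were limited to −log10 q of 3 or more. Limiting both lists also removes most possible partners. With only the counted list so limited, the share was 20.0% and 18.9%. No rotation was made for these settings.

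**Figure D3:**
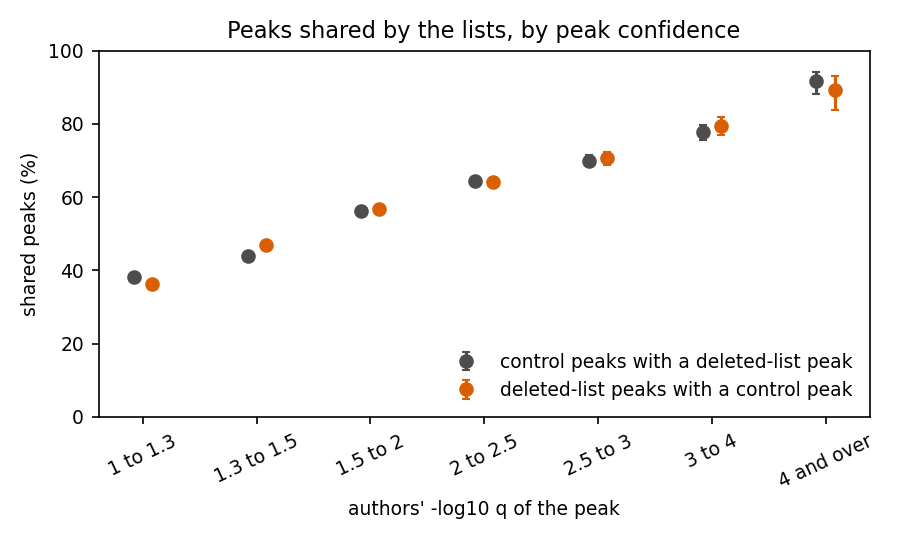
Percent of peaks that overlap a peak of the other list (y axis) by class of the authors' −log10 q (x axis), for control peaks (grey) and deleted-list peaks (orange); bars are 95% Wilson intervals, which cover counting error only. The percent is 38.2% and 36.3% in the lowest class and 91.8% and 89.2% in the highest.

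Zinc finger genes were covered more in the deleted list, relative to matched genes, and clustered protocadherins were mixed. The 397 Zfp genes, many of which encode DNA-binding repressors in clusters, had a mean window coverage of 10.9% in the control list and 12.6% in the deleted list. Of them, 157 were covered more in the deleted list, 76 less and 164 equally, and the list's mean lay at percentile 100 of the matched random lists. The list's median difference was 0 points, at percentile 50. The median of the matched random lists was also 0, so that percentile is a tie and does not test the list. Zfp873 was covered at 43.6% and 72.2%, and Zfp493 at 35.4% and 19.9%. The 39 clustered protocadherins, cell adhesion genes in arrays on chromosome 18, had means of 20.0% and 22.3%, with 25 members covered more, 11 less and 3 equally. Their percentile was 98.8. The 22 beta genes differed by -0.841 points on average and the other 17 genes by 6.46. Pcdhb8 was covered at 25.2% and 69.0%, and Pcdhb10 at 41.7% and 12.6%. At −log10 q of 3 or more the Zfp mean turned to -0.533 points (percentile 94.3), and Pcdhb8 differed by -6.95 points. At 2 or more Pcdhb8 differed by 24.1 points. The protocadherin mean stayed higher in the deleted list at 2 or more, by 0.435 points (percentile 99.8), and at 3 or more, by 0.725 (99.9). The median difference of the protocadherins was 5.22 points (99.99). The protocadherin mean turned to -3.97 points (percentile 48.4) with 1 gene per 500 kb, which left 3 genes, and to -0.526 (86.7) at gene ends. Its percentile was 96.1 with matching on gene density and 96.9 without chromosomes 6, 14, X and Y. No protocadherin of the list lies on those chromosomes. That last change came from the random lists, whose median went from -2.25 to -1.31 points.

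**Figure D4:**
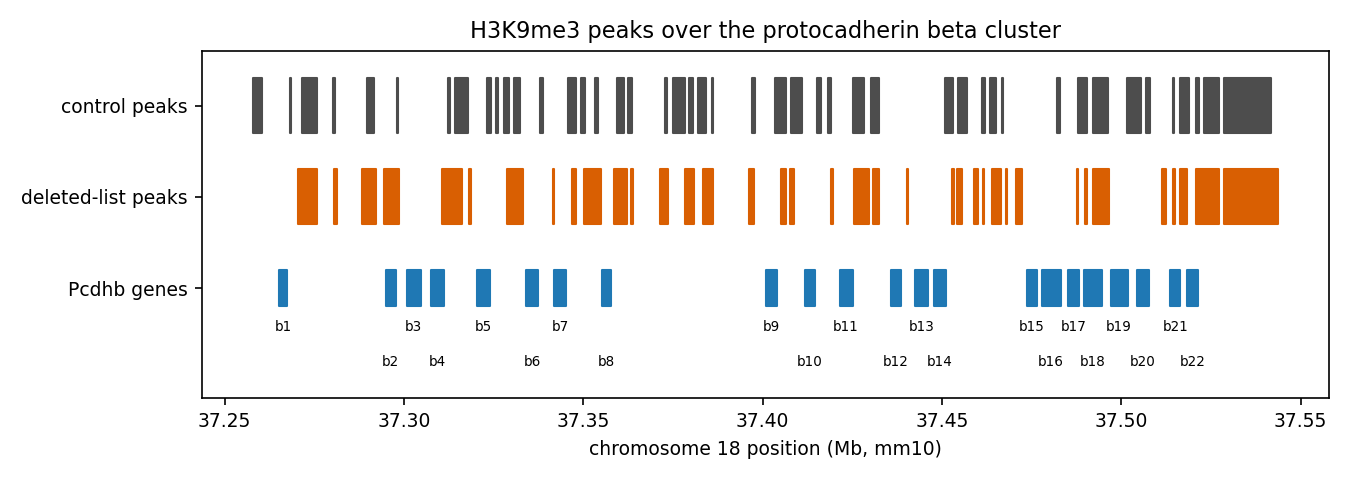
H3K9me3 peaks of the control list (grey) and the deleted list (orange) over the protocadherin beta genes (blue, b1 to b22) on chromosome 18, with mm10 position in Mb on the x axis; the region was chosen after its values were seen. Of the 22 genes, 11 were covered more and 11 less in the deleted list, and both lists covered 27.5% of the span from 37264998 to 37521419.

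Olfactory and vomeronasal receptor genes, which encode odorant and pheromone receptors, had lower mean coverage in the deleted list, which for vomeronasal receptors was mostly a difference on chromosome 6. The 1110 olfactory receptors had means of 19% and 16.9%, with 380 covered more, 500 less and 230 equally, and a percentile of 98.8, since matched random lists fell by 3.09 points at the median. That percentile was inside the central 95% at −log10 q of 2 (92.6) and 3 (87.3) or more. It was also inside with 1 gene per 500 kb (92.2) and with matching on gene density (92.7). Without chromosomes 6, 14, X and Y it was 69.0, with the list mean at -2.25 points and the random median at -2.48. By the median it was 50, a tie at 0 points with the random lists, which does not test the list. At −log10 q of 3 or more the mean was higher in the deleted list, by 0.0112 points. The 355 vomeronasal receptors had means of 16.7% and 14.3%, with 116 covered more, 135 less and 104 equally, and a percentile of 4.25, inside the central 95%. Without chromosomes 6, 14, X and Y they had 15.7% and 15.5%, and a percentile of 56.0. Olfr901 was covered at 67.1% and 4.26%, and Olfr654 at 5.97% and 58.9%. Vmn1r11 on chromosome 6 was covered at 100% and 43.7%, and Vmn1r-ps103 on chromosome 13 at 0% and 50.4%.

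Genes of the muscle lineage carried little of the mark in either list. The 36 myogenic regulators had means of 0.0645% and 0.0463%, with 2 covered more, 2 less and 32 equally, and a percentile of 2.16. Without chromosomes 6, 14, X and Y their mean difference turned from -0.0181 to 0.0389 points (percentile 10.1). The percentile was 3.23 at the same number of peaks, 6.53 at gene ends and 26.4 at −log10 q of 2 or more. It was 33.5 at −log10 q of 3 or more and 50 by the median. In these last 2 settings the list and the random median were both at 0 points, so neither tests the list. The 41 muscle contractile genes had means of 0.162% and 0.218% (percentile 24.4), and the 38 markers of other cell types in muscle 0.683% and 0.724% (29.9). Means were 0.319% and 0.196% for 39 Hox genes (percentile 6.24), 0.155% and 0.383% for 33 Rhox genes (53.2), and 0.758% and 0.502% for 80 ribosomal protein genes (6.76). Rpl39l, in that list, was covered at 23.0% and 9.46%. The 56 imprinted genes had means of 1.67% and 1.80% (30.2), the 41 germline genes 0.846% and 0.850% (18.6), and the 51 chemokine and cytokine genes 0.339% and 0.543% (33.5). The imprinted list turned to -0.565 points (percentile 2.49) at gene ends, and the chemokine and cytokine list to -0.385 (2.37) with 1 gene per 500 kb. The 50 genes of nucleic acid sensing and interferon response had means of 0.756% and 0.617% (8.36), and the 35 genes of the H3K9 methylation machinery 1.68% and 1.42% (14.5). The mean of the latter turned to 0.0495 points without chromosomes 6, 14, X and Y and to 0.0717 at −log10 q of 2 or more, and that of the former to 0.157 at gene ends. The 109 keratin and keratin-associated genes had means of 3.84% and 5.32% (87.3), with Krtap4-16 at 8.47% and 33.0% and Krtap8-1 at 34.9% and 4.83%. Their mean turned to -0.410 and -0.0847 points at −log10 q of 2 and 3 or more. The random medians there were also negative, at -0.979 and -0.137 points, and the percentiles were 89.3 and 61.0. The 30 neuronal genes had means of 8.01% and 6.93% (5.84), with Cntnap2 on chromosome 6 at 29.2% and 12.5%. Without chromosomes 6, 14, X and Y the neuronal means were 6.96% in both lists, a difference of 0.00589 points (percentile 19.3). In all, 4 of the 17 lists lay outside the central 95%, and 1 did so without chromosomes 6, 14, X and Y. Chance would give 0.85 for lists of independent genes, a number that does not allow for clustered genes that share peaks.

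**Figure D5:**
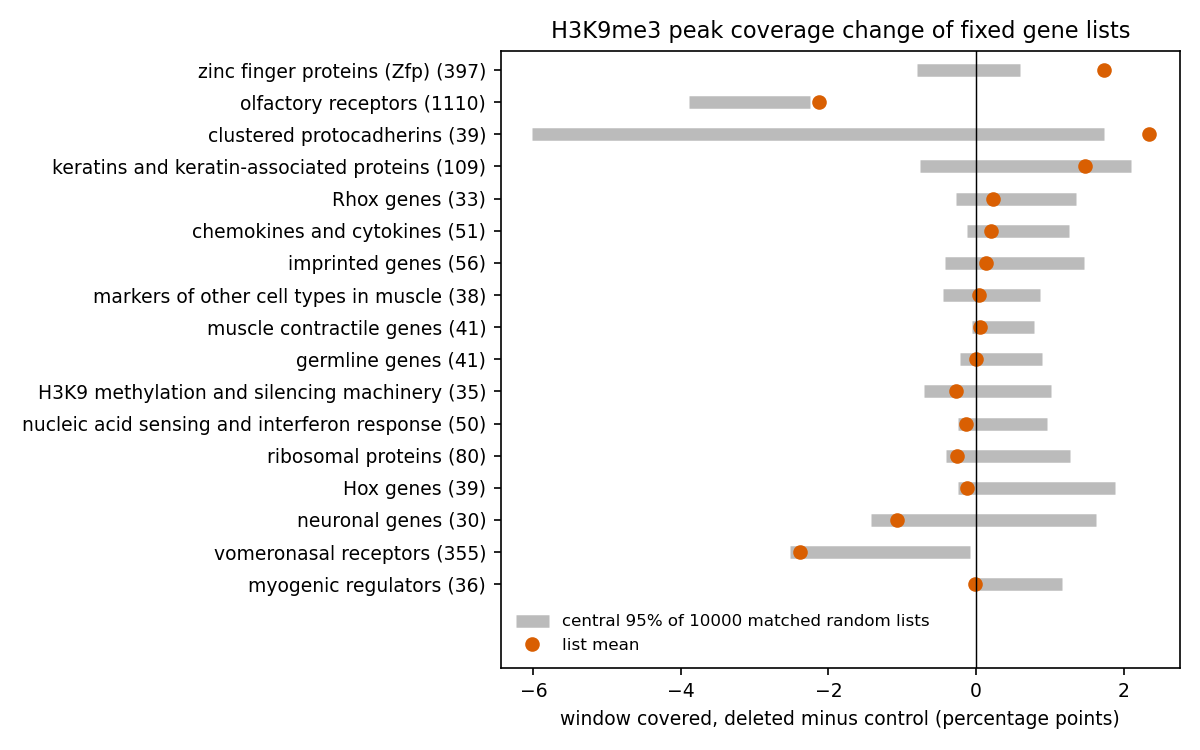
Mean difference in percent of gene window covered, deleted minus control, in percentage points (x axis), for the 17 gene lists (y axis, with the number of genes); orange points are list means and grey bars the central 95% of 10000 matched random lists. Zinc finger proteins, clustered protocadherins, olfactory receptors and myogenic regulators lie outside their bars.

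At gene ends, peaks were present in both lists for 2314 of 21887 protein-coding genes, in the control list only for 748 and in the deleted list only for 946. Genes with control-only peaks at their ends were ranked by the sum of fold times overlapped bases, which grows with the length covered. Those ranked highest included Klrh1 and Klri2, killer cell lectin-like receptor genes on chromosome 6. Their windows were covered at 43.9% and 4.88%, and 49.3% and 2.73%. Also on chromosome 6 were Tas2r124, a taste receptor gene, at 66.5% and 4.82%, and Vmn1r28 at 40.4% and 0%. On other chromosomes were Pcdhb20 (36.0% and 7.78%), Cd209b (26.5% and 1.70%), Slc10a2 (11.9% and 2.41%) and the olfactory receptors Olfr1176 (59.0% and 0%), Olfr1240 (40.6% and 3.03%), Olfr836 (47.4% and 4.54%), Olfr114 (36.7% and 25.4%) and Olfr901. The genes with the highest such sum in deleted-only peaks were Vmn1r-ps103, Vmn1r195 (0% and 46.5%), Zscan4d (0% and 38.6%), Oog3 (9.50% and 40.5%), Olfr703 (8.74% and 45.4%), Defb11 (6.24% and 48.3%), Hs3st2 (3.16% and 18.7%) and Trim30a (6.61% and 17.4%). Many of these differences were absent among peaks of higher confidence. Of 31 named genes that differed between the lists, 17 were at 0 points at −log10 q of 2 or more and 28 at 3 or more. At −log10 q of 3 or more only 1.83% of control and 0.987% of deleted-list peaks remained, and at 2 or more 18.8% and 11.5%. With so few peaks left, a difference of 0 points says little about a gene. At 2 or more Olfr1176 differed by -3.80 points, Trim30a by -1.67 and Tas2r124 by -38.1.

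Among 27210 bins of 100 kb, 127 lost at least 20 percentage points of coverage in the deleted list and 10 gained as much, and 118 of the 127 were on chromosome 6. The largest losses were over Cntn6, at 49.0% and 9.17% from 104700001 to 104800000 and at 51.2% and 15.2% from 104500001 to 104600000, and over Cntnap2, at 48.1% and 11.4% from 46200001 to 46300000. A bin with Klra7 and Klra10 stood at 48.3% and 13.4%, and a gene-poor bin from 79000001 to 79100000 at 57.6% and 18.8%. The largest gain, on chromosome 13 from 61100001 to 61200000, was over the cathepsin genes Ctsr and Cts6, at 37.2% and 65.1%. Other gains were over Btbd35f25 on X (15.6% and 42.1%), Agbl4 on chromosome 4 (25.6% and 48.0%), a cluster with Olfr695, Olfr697, Olfr698 and Olfr699 on chromosome 7 (16.2% and 38.5%) and a bin on chromosome 10 whose nearest gene was Ipmk (10.9% and 33.3%). Without chromosomes 6, 14, X and Y, 9 bins lost and 9 gained, and the losses included bins over Sgcz on chromosome 8 (41.0% and 12.6%) and Ncam2 on chromosome 16 (39.0% and 15.9%).

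Most peaks lay outside genes. Peaks with a midpoint in a protein-coding gene made up 21.3% of the control list (Wilson interval 21.1 to 21.6%) and 21.6% of the deleted list (21.3 to 21.8%), while such genes took up 38.7% of the chromosomes. Peaks over 5 kb from any gene made up 61.3% and 60.9%, against 43.5% of the chromosomes. The control peaks of highest fold with no deleted-list peak lay outside protein-coding genes, on chromosomes 15 (fold 4.18), 6 (4.16), 8 (4.08), 4 (3.96) and 2 (3.93). The nearest protein-coding genes were Abra at 160.1 kb, Pdzrn3 at 223 kb, Aga at 23.8 kb, Manea at 659.9 kb and Prdx6b at 8.34 kb. Those of the deleted list alone were on chromosome 11 in Sfi1 (fold 4.88) and on chromosomes 15 (4.50), 12 (4.36), 7 (4.17) and 4 (4.09), where the nearest genes were Ptger4 at 53.9 kb, Dnajb9 at 656 kb, Eif3f at 33.0 kb and Cylc2 at 91.7 kb. These folds are the authors' values and are not compared between the lists.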

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

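Peaks on unplaced scaffolds, which enter no comparison of the report, covered 376.5 kb in the deleted list and 305 kb in the control list. There were 185 such peaks on 26 scaffolds in the deleted list and 155 on 27 scaffolds in the control list. This was a signal outside the main chromosomes that was higher than in the control, and with 1 library per group the difference was not tested. No group had enough libraries for a search for samples that stand apart.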

How the results depend on the processing

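The settings without chromosomes 6, 14, X and Y, at −log10 q of 2 or more, with 20000 peaks per list and with matching on gene density were chosen after seeing the data. Of 423 alternative values for 73 results, 261 kept their size, or for a gene list its side of the threshold. The sign of a list's mean turned in 23 of 152 alternatives, over 13 lists, and 15 of these kept their side of the threshold. The cause was not tested for any other value, except that stricter thresholds leave fewer peaks and joining makes longer ones. Leaving out a replicate was not possible with 1 library per group. No paired analysis was possible because each group had 1 library. Repeat content was not run, and promoter windows could not be placed. Sequencing depth is unknown, which limits every comparison of list size.

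At −log10 q of 3 or more the lists held 1937 control and 1120 deleted-list peaks (deleted minus control -817) covering 3.89 and 2.48 Mb (log2 ratio -0.65). At 2 or more they held 19912 and 13039 (-6873) covering 30.9 and 19.8 Mb (-0.64). Peaks at or above the median fold of their list numbered 52855 and 56753 (3898 more in the deleted list) covering 74.6 and 75.9 Mb, and peaks joined within 5 kb numbered 53029 and 55767 (2738 more) covering 264 and 274 Mb. Without X and Y the log2 ratio of covered length was -0.0225.

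The control and deleted-list shares of peaks without a partner were 87.1% and 77.9% with both lists at −log10 q of 3 or more, and 81.9% and 72.5% at 2 or more. With only the counted list limited they were 20.0% and 18.9% at 3, and 32.9% and 33.2% at 2. They were 48.9% and 48.4% at the same number of peaks, 36.9% and 39.6% with peaks joined within 5 kb, 46.7% and 48.5% without X and Y, and 45.5% and 49.4% without chromosomes 6, 14, X and Y. Requiring 50% of the peak gave 68.1% and 68.7%, and allowing 5 kb gave 15.5% and 17.9%. Base overlap was 39.2% with peaks joined within 5 kb and 14.9% at −log10 q of 2 or more. It was 2.17% with only the control list at 3 or more and 1.46% with only the deleted list so limited. The last 2 values could not come near the main value, because 1 list was cut to 3.89 or 2.48 Mb. They do not measure a loss of sharing.

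Shares in protein-coding genes were 20.5% and 21.0% by covered bases, 25.6% and 27.4% at −log10 q of 3 or more, and 21.9% for the deleted list without chromosomes 6, 14, X and Y. A flank of 1 kb held 1.92% and 2.04% of peaks. At −log10 q of 3 or more, gene ends had peaks in both lists for 55 genes, in the control list only for 108 and in the deleted list only for 53, and with windows of 1 kb, 1217 genes had peaks in both. Bins that lost and gained numbered 3 and 2 at −log10 q of 3 or more, 384 and 127 at 50 kb, and 14 and 0 at 500 kb, and 9 lost without chromosomes 6, 14, X and Y.

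The difference on chromosome 6 was -0.172 points at −log10 q of 3 or more, -2.15 at 2 or more and -1.81 with 20000 peaks per list. On X it was 0.0102, 0.0842 and 0.202 points. On chromosome 14 it was -0.0015, -0.0210 and -0.0082, and -0.101 at the same number of peaks. Gene lists outside the central 95% numbered 1 at −log10 q of 3 or more, 1 without chromosomes 6, 14, X and Y and 1 by the median. They numbered 2 at −log10 q of 2 or more and 2 with matching on gene density. By the median, all lists but the protocadherins and neuronal genes tied at 0 points with their random lists, so that count tests few lists. The Zfp percentile was 94.3 at −log10 q of 3 or more (mean -0.533 points) and 50, a tie, by the median. The protocadherin percentile was 48.4 with 1 gene per 500 kb (mean -3.97 points) and 86.7 at gene ends (-0.526). Imprinted genes at gene ends (2.49) and chemokines with 1 gene per 500 kb (2.37) left the central 95% with the sign of their mean turned. Among 136 alternative values for 34 named genes, 78 kept their size, 56 moved and 2 changed direction, and 28 of the 31 that differed were at 0 points at −log10 q of 3 or more: Pcdhb8 differed by -6.95 points at −log10 q of 3 or more and Trim30a by -1.67 at 2 or more.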

Other observations

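Receptor gene clusters differed by chromosome. The 60 vomeronasal receptors on chromosome 6 had mean window coverage of 21.6% in the control list and 8.80% in the deleted list, and the 46 on chromosome 17 had 31.6% and 24.0%. The 178 on chromosome 7 had 11.2% and 11.5%, with 48 covered more and 40 less. The 36 on chromosome 13 had 15.5% and 23.8%, with 26 covered more and 9 less. The 287 olfactory receptors on chromosome 2 had 31.8% and 26.1%, and the 130 on chromosome 9 had 19.5% and 13.2%, while the 24 on chromosome 4 had 4.13% and 9.63%. The 239 on chromosome 7 had 21.1% and 22.3%, with 100 covered more and 117 less. Among Zfp genes, the 93 on chromosome 7 had 6.96% and 8.97%, with 34 covered more and 12 less, and the 27 on chromosome 4 had 28.8% and 32.1%, on the autosomes with the highest whole-chromosome ratios (1.23 and 1.16). The 46 on chromosome 17, whose whole-chromosome ratio was 1.01, had 16.3% and 18.8%, with 21 covered more and 11 less. The 27 on chromosome 2, whose ratio was 0.980, had 6.89% and 9.34%, with 10 covered more and 4 less. The 19 on chromosome 5 had 14.8% in both lists, the 20 on chromosome 9 had 13.3% and 13.7% with 9 covered more and 8 less, and the 11 on chromosome 18 had 5.33% and 5.73% with 3 more and 5 less. The 5 on chromosome 3 had 5.95% and 4.73%, and the 11 on chromosome 15 had 1.01% and 0.679%.

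Gene-dense segments had higher deleted-to-control ratios. Over 211 segments of 10 Mb on the 17 autosomes other than 6 and 14, the Spearman correlation of the ratio with the number of protein-coding genes was 0.487, and it was positive in 17 of 17 chromosomes. The median ratio was 0.989 in the segments of low gene density, 1.06 in the middle and 1.20 in those of high density. Mean control coverage was 7.45% in segments of low density, 4.21% in the middle and 4.28% in those of high density. It was thus alike in the middle and at high density, where the median ratio still differed. Over all segments its Spearman correlation with the ratio was -0.336. Segments are not independent replicates, and this relation was found after seeing the data. The peaks of highest −log10 q in both lists were near position 98666603 on chromosome 2 and from 19415757 on chromosome 14, at −log10 q of 1505 and 679 in the control list. The authors' fold of these peaks in the control list was only 1.44 and 2.43, below that list's median of 2.57. The input libraries were not analysed, so whether these peaks reflect the mark was not tested.

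In the weighing of the chromosomes that stood apart, the patterns were noticed first. Ranges and percentiles of the other autosomes, or of segments elsewhere, are those of the 17 autosomes without 6 and 14. The test of Setdb1 deletion on chromosome 6, the regional test on chromosome 14, the setting of 20000 peaks per list, the share of strong peaks on chromosome 14 and the rule that sets aside the fold tests were chosen only after the result was seen. Fold was tested as a sign of a DNA dose that differs between ChIP and input. The peak caller keeps only peaks past its threshold, and the chromosomes' median folds of shared peaks ranged over only 2.35% of their median in the control list and 5.01% in the deleted list, so under 10% these tests were taken to decide nothing in either direction. Those ranges leave out Y, which had only 10 and 11 shared peaks; with Y they were 23.3% and 10.0%, and the rule would not apply. Without the rule, the tests as first written would have spoken for a dose on chromosome 6 and against one on chromosome 14.

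Chromosome 6 was covered more in the control list. A regional domain is argued against, since its highest ratio of any 10 Mb segment was 0.627. The 5th percentile on the other autosomes except 14 was 0.855. Segments of the sparsely covered chromosome 14 had ratios from 0.430 to 1.33. A difference in size or threshold between the whole lists is argued against too, while a threshold effect confined to chromosome 6 was not tested. The ratio was 0.501 at the same covered length, but that setting left out only 639 deleted-list peaks, so the ratio could hardly change. It was 0.337 with 20000 peaks per list, where the lowest other autosome except 14 was at 0.851 and chromosome 14 at 0.791. The fold test for a DNA dose came out as predicted by a narrow margin, with a median of 2.630 on chromosome 6 against 2.626 on the next highest autosome, and by the rule above it leaves that explanation open. Setdb1 deletion also cannot be told apart from the library, with 1 library per group. Chromosome 6 of the deleted list, at 5.28%, lay within its other autosomes except 14 (3.19 to 7.86%). That of the control list lay outside its own (2.78 to 7.77%). By coverage it was thus the control list that stood apart; the fold, set aside above, was lowest of the autosomes in the deleted list (2.539).

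Chromosome X was covered more in the deleted list. A regional domain is argued against by the lowest segment ratio of 1.80, above the 95th percentile of 1.55 elsewhere. A difference in size or threshold between the whole lists is argued against by a ratio of 2.47 with 20000 peaks per list. The highest autosome there was at 1.24. At the same covered length the ratio was 2.26, with the highest autosome at 1.23. That setting left out only 639 deleted-list peaks, so the ratio could hardly change. A threshold effect confined to X was not tested and stays open. At −log10 q of 3 or more, X had only 0.0960 control and 0.138 deleted-list peaks per Mb. Chromosome 19 had 0.567 and 0.275. The fold test for a DNA dose met neither prediction, at a median of 2.658 against 2.659 for the highest autosome except 14, which had 2.670. A dose difference may still account for the higher coverage of X. No biological explanation was tested, and the sex and chromosome number of the cultures, not given in the sources used here, could differ between them and would change what the ratios of X and of chromosome 6 mean.

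Chromosome 14 was sparsely covered in both lists. A regional gap is argued against, since its highest segment was covered at 0.778% in the control list, below the 5th percentile of 1.15% elsewhere. A threshold effect stays open: chromosome 14 had 0.0342 control peaks per Mb at −log10 q of 3 or more, below the lowest other autosome at 0.567, as written in advance against it, but a stricter threshold can only remove peaks, and the strong share of its peaks was also low (0.612% against 1.29 to 2.53%). The fold test met the outcome written in advance as speaking against a DNA dose, with a median of 2.624 against 2.594 over the other autosomes; that outcome was wrongly chosen, because peaks that pass a threshold on a depleted chromosome need a fold as high as elsewhere, so a dose difference may remain. A dose shared by ChIP and input was not tested, and no biological explanation was tested.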
